A study of Mus musculus with 5 samples.

How the data were processed

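Gene expression was measured with Affymetrix arrays on total RNA of D2SC/1 cells, a mouse dendritic cell line. RNA was purified on RNeasy columns and labelled with biotin by the GeneChip whole-transcript terminal labelling chemistry, per the labels' protocols. Cells were cultured with thawed virus-containing supernatant on retronectin-coated dishes, per the labels' protocols. The virus carried either the active form of the transcription factor LUMAN, called LUMANdp, or green fluorescent protein (GFP) as the control. Cells were taken at 6 h and at 18 h, and untreated cells stood for time 0. This made 5 groups of 1 array each. There were therefore no replicates, and no difference between 2 arrays has a replicate check. Group, and time for the infected arrays, were taken from the sample titles. The title of the untreated array gives no time.

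The deposited values are log2 expression values, 1 per probe set and array, made with RMA (robust multi-array average) and Partek, per the submitters' processing notes. Versions and the probe set level of the summary are not given in the sources used here. On these arrays the log2 values ran from 2.41 to 14.1, with array medians between 4.95 and 5.01. No detection call was used. Precision is limited by the number of arrays. Signal over background was judged from 838 olfactory, vomeronasal, trace amine and bitter taste receptor genes, which are not used in this cell type: their levels over the arrays had a median of 3.53 and a 95th percentile of 4.64.

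The table held 23301 probe sets, with no missing values and no duplicate identifiers. GEO's platform annotation paired 14996 of them with 1 gene symbol and 1019 with several, and 7286 had no name in the annotation used here. Of these 7286, 6546 had an identifier number under the lowest named one. What the probe sets with no name measure is not given in the sources used here, and they may not all measure genes. Of the named probe sets, 14941 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols differed from it. That table was used for names and for genomic span only, and no coordinates are given because no genome was used here. Probe sets with 1 symbol covered 14860 genes. For the 135 genes with more than 1 probe set, the probe set with the highest mean over the 5 arrays stood for the gene. A gene entered the comparisons if its highest value over the 5 arrays reached the median of all values in the table (4.97), which left 8584 genes.

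Each comparison between 2 arrays was the difference of their log2 values. Genes at least 1.5-fold higher or lower were counted, as a rule of size and not a test, so no p-value is given for them. LUMANdp was compared with GFP at the same time, and each infected array with the untreated array. Agreement between the times was set against n1 × n2 / N, the overlap of independent lists. The comparisons of GFP with untreated cells share the untreated array, so their overlap was also set against 100 draws of 3 simulated unchanged arrays.

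An additive model over all 5 arrays (virus, time, and infected against untreated) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Its only residual degree of freedom (1) is the virus-by-time interaction. Its p-values therefore set each effect against an error taken from the departure between times and borrowed across genes, and not against the spread between replicates. The fit was tested on simulated data with 8584 genes, using noise taken from the robust spread of the LUMANdp minus GFP differences. It recovered 100 of 100 genes with a log2 change of 1 and 100 of 100 with a log2 change of 2, and called 9 unchanged genes. The rule of 1.5-fold at both times recovered 97 and 100 of them and 0 unchanged genes, whereas 47 unchanged genes passed 1.5-fold at 6 h alone and 59 at 18 h alone. The simulated changes were the same at both times, as the model assumes. These recoveries therefore do not hold for changes that differ between the times. The simulated noise was normal, with a robust spread taken from the compared arrays themselves, so it lacks any larger outliers. The counts of unchanged genes may thus be too low and do not give the share of noise among the genes past 1.5-fold.

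Gene lists were described by the median difference of their members past the filter, as a percentile among the medians of 10000 random lists of the same size matched on mean expression in 10 bins. A list counted as outside the middle 95% below percentile 2.5 or above 97.5, and lists with under 5 members were not ranked. Of 45 lists, 10 of them cell type markers, 38 could be ranked. By chance 1.9 per comparison would lie outside if the genes within a list varied independently. Random lists do not hold any joint variation of a list's members, so more could lie outside by chance. These percentiles describe these arrays and are not p-values.

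Named genes follow a rule. Creb3 and Apoa4 are always named. For LUMANdp against GFP they are the 10 highest and 10 lowest genes at each time and up to 10 each way past 1.5-fold in the same direction at both times. For GFP against untreated they are the 8 highest and 8 lowest at each time, and for the difference of the LUMANdp effect between times the 5 highest and 5 lowest. From a described list, up to 4 members with the largest absolute difference and any member past 1.5-fold may be named. Genes with only a predicted, clone or accession name were left out of the rankings. The groups, comparisons, size rule, filter, gene lists, naming rule and alternatives, except those named below as added, were chosen before the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all other steps.

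Alternatives were a 2-fold rule, no filter, a filter at the 75th percentile of all values, quantile normalization of the 5 arrays, centring of each difference on its loess curve against mean intensity, the mean over a gene's probe sets, all probe sets counted alone, other control arrays, other eBayes settings, and other rules for the lists. Removal of a loess trend on genomic span, counts without sensory receptor genes, and the mean of both GFP arrays as control for the count at both times were added after the data were seen. The control arrays averaged over different times are not matched on time. Differences from them also hold part of any change in GFP cells between the times. Probe sets with no name or several names entered no comparison by gene. They entered the alternative that counts all probe sets, and those with no name were also counted on their own for LUMANdp against GFP. No split of the arrays into other groups was possible with 1 array per group.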

Results

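The series asked which genes respond to LUMAN, the product of Creb3, in a dendritic cell line. LUMAN is a basic leucine zipper transcription factor that is held in the endoplasmic reticulum (ER) membrane until its active part is released. D2SC/1 mouse dendritic cells were infected with a retrovirus for the active form (LUMANdp) or for GFP, and expression was measured at 6 h and 18 h and in untreated cells, with 1 array in each of the 5 groups. Over all probe sets the arrays correlated with one another at 0.984 to 0.992, and the closest pair was GFP and LUMANdp at 6 h. Markers of macrophages and monocytes were measured above the filter for 15 of 16 genes with a probe set and conventional dendritic cell genes for 7 of 17. The same held for 4 of 14 T cell, 3 of 19 fibroblast, 1 of 9 natural killer cell, 1 of 6 erythroid and 0 of 11 B cell markers.

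Creb3 was higher with the LUMANdp virus than with the GFP virus at both times. Its log2 level (probe set 6913012) was 7.43 in untreated cells, 7.27 with GFP and 9.07 with LUMANdp at 6 h, and 8.49 with GFP and 10.17 with LUMANdp at 18 h. The difference was 1.81 at 6 h (3.50-fold) and 1.69 at 18 h (3.22-fold). In the GFP culture at 18 h, Creb3 was itself 2.08-fold above the untreated level. Whether virus-encoded transcript hybridises to this probe set is not given in the sources used here. Apoa4, the gene named in the series title, encodes an apolipoprotein of triglyceride-rich lipoproteins. Its log2 level (probe set 6988771) was 4.52 in untreated cells, 4.71 with GFP and 4.70 with LUMANdp at 6 h, and 4.82 with GFP at 18 h, close to the 95th percentile of sensory receptor genes (4.64). With LUMANdp at 18 h it was 8.11, 9.79-fold above GFP at that time. The LUMANdp minus GFP difference of Apoa4 was thus -0.01 at 6 h and 3.29 at 18 h.

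**Figure D1:**
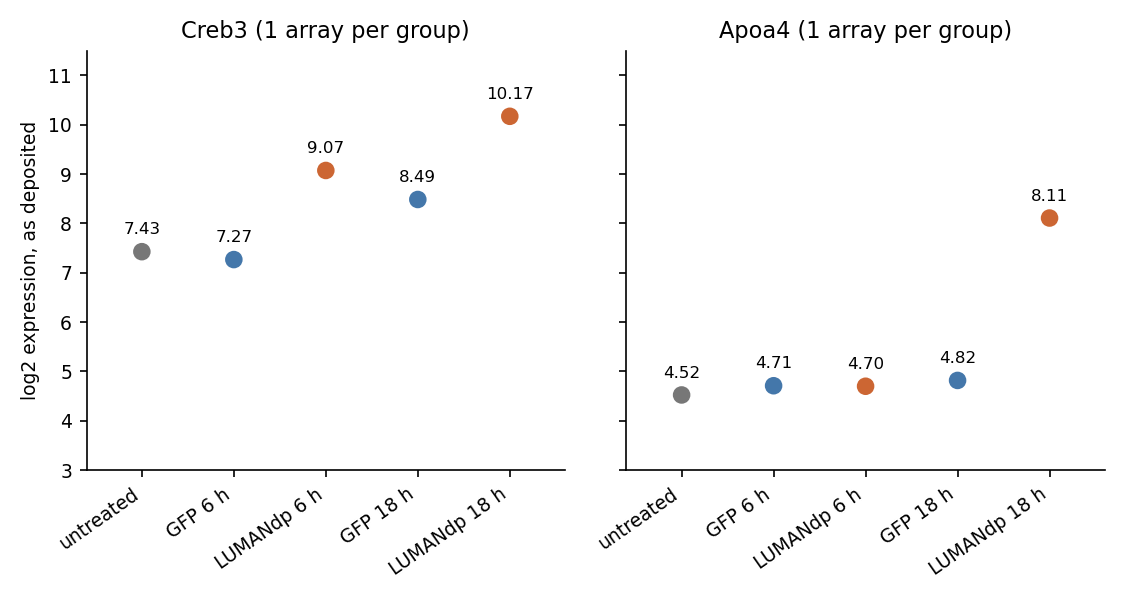
Deposited log2 expression (vertical axis) of Creb3 and Apoa4 on each of the 5 arrays (horizontal axis), 1 point per array, with no error bars because each group is 1 array. Creb3 was higher with LUMANdp than with GFP at 6 h (9.07 against 7.27) and 18 h (10.17 against 8.49), whereas Apoa4 stood apart only with LUMANdp at 18 h (8.11).

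At 6 h, 179 genes were at least 1.5-fold higher and 18 at least 1.5-fold lower in LUMANdp than in GFP cells. Over all probe sets past the filter, with or without a name here, the split was 471 to 472. What the probe sets with no name measure is not known here, so this split may not be one of genes. After Creb3, the highest differences belonged to Supt4a, a transcription elongation factor subunit (1.73 on the log2 scale), and Spcs1, a subunit of the signal peptidase complex (1.26). They were followed by the glutathione transferase Gsta3 (1.21), the kinase Cdk10 (1.16), the nucleotidase Nt5c2 (1.13), Fdps of the cholesterol pathway (1.12), Tmem9 (1.11), Gtf2h4, a subunit of a general transcription factor (1.08), and Nubpl, which assembles respiratory complex subunits (1.07). With the mean of both GFP arrays as control, Gsta3 (0.57), Cdk10 (0.56), Gtf2h4 (0.39), Tmem9 (0.37), Nt5c2 (0.33) and Nubpl (0.29) did not pass 1.5-fold. That control is not matched on time, so these values also hold part of the change in GFP cells from 6 h to 18 h. The lowest was Ahcy, which hydrolyses S-adenosylhomocysteine (-1.21), followed by Vmn1r183 (-1.07), the centrin Cetn4 (-1.07) and the histone gene H4c14 (-0.92). Olfr71, Olfr352, Rnf24, Olfr667, Sfn and Olfr484 completed the 10 lowest, at -0.82 to -0.71. With that control, Olfr71 (-0.55), Olfr484 (-0.43), Rnf24 (-0.39), Sfn (-0.29) and Vmn1r183 (-0.02) did not pass. Of these 10 genes, 5 are sensory receptor genes, which are not used in this cell type. Fdps with GFP (4.50) and Olfr71, Olfr352 and Olfr667 with LUMANdp were under 4.64, the 95th percentile of sensory receptor genes, so that background limits how exactly their differences and ranks are known.

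Of the 38 ranked lists at 6 h, 10 lay above the middle 95% of random lists and 0 below. Genes of mitochondrial oxidative phosphorylation had a median difference of 0.26 (percentile 99.98), with 17 of 18 members above 0 and 1 past 1.5-fold, Cox5a at 0.59. Cytosolic ribosomal proteins had a median of 0.33 over 6 members (percentile 99.7), with Rplp0 highest at 0.49. The proteasome list had a median of 0.19 (percentile 99.7) although Psma3 was lower, at -0.69. MHC class I presentation had a median of 0.25 (percentile 99.4), led by the immunoproteasome subunits Psmb8 (0.66) and Psmb9 (0.52). The signal peptide and translocon list (median 0.20, percentile 99.2) was led by Spcs1 and Ssr4 (0.57), and cholesterol biosynthesis (median 0.18, percentile 98.9) by Fdps and Sc5d (0.60). Macrophage and monocyte markers moved the same way, with a median of 0.18 (percentile 99.0) and C1qb highest at 0.45. MHC class II presentation (median 0.26, percentile 98.2), Golgi and COPI transport (median 0.17, percentile 98.1) and the type I interferon response (median 0.18, percentile 97.8) were also above. Most members of these lists stayed under 1.5-fold, and 0 members of the ribosomal, MHC class II and macrophage lists passed it. In GFP against untreated cells at 6 h, oxidative phosphorylation (median -0.26, percentile 0.0) and the proteasome (-0.11, 1.44) lay below the random range. The macrophage and interferon lists lay above it there, and the others inside. The oxidative phosphorylation and proteasome differences thus came with a low level on the GFP 6 h array. So did those of Spcs1 (-1.01 in GFP against untreated) and Fdps (-0.72).

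The 6 h differences followed genomic span. Spearman's rho across 8570 genes, which are not independent replicates, was -0.32, and over 5 bins of genes by span the median difference went from 0.13 in the shortest to -0.06 in the longest. With that trend removed, 99 genes were higher and 35 lower, and the Golgi, translocon, cholesterol, MHC class II and macrophage lists came inside the middle 95% (percentiles 91.1 to 95.1). By the mean instead of the median, the Golgi (percentile 89.6), proteasome (94.9) and MHC class II (96.7) lists came inside. The MHC class II list also did so against random lists not matched on expression (97.0) and after centring on mean intensity (96.0), and the interferon list with the mean over a gene's probe sets (97.47). With the mean of both GFP arrays as control, 94 genes were higher and 22 lower. At 18 h the rho of LUMANdp against GFP with genomic span was 0.14, of the other sign. Against untreated cells it was 0.14 at 6 h and -0.13 at 18 h for GFP, and -0.06 and -0.03 for LUMANdp. The larger trends against untreated cells were thus those of the GFP arrays, in opposite directions, which limits both comparisons of LUMANdp with GFP.

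At 18 h, 162 genes were at least 1.5-fold higher and 105 at least 1.5-fold lower in LUMANdp than in GFP cells, and genes of transport between ER and Golgi stood out among the higher ones. Apoa4 (3.29) and Nfyc, a subunit of the NF-Y transcription factor (2.30), were highest, then Sec23a (1.73) and Sec24d (1.71), which form the inner coat of ER-derived COPII vesicles. Creb3 (1.69), Atg2a of autophagosome formation (1.60), Lysmd1 (1.60), Olfr1286 (1.52), Tas2r113 (1.33) and Gbf1, which activates Arf proteins at the Golgi (1.28), followed. Nfyc was as high with LUMANdp at 18 h (6.13) as in untreated cells (6.13) and low with GFP at 18 h (3.83), so that its difference from GFP came with a control level under 4.64, the 95th percentile of sensory receptor genes. Background limits how exactly the sizes and ranks of Apoa4, Nfyc and the sensory receptor genes are known. The sensory receptor genes Olfr1286 and Tas2r113 reached only 4.98 and 5.20.

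The Golgi and COPI transport list had a median of 0.39 at 18 h (percentile 100), with all 16 members above 0 and 6 past 1.5-fold. These were Gbf1, the GTPase Arf4 (1.01), the Golgi matrix protein gene Golga2 (0.93), Arfgap1 (0.72) and the COPI coat genes Copa (0.64) and Copb2 (0.59). The ER-to-Golgi transport list had a median of 0.12 (percentile 99.7), with 15 of 16 members above 0 and 4 past 1.5-fold. The latter were Sec23a, Sec24d, Sec24a (1.16) and Sec16a, a scaffold of ER exit sites (0.82). Signal peptide and translocon genes had a median of 0.10 (percentile 99.9) with 0 of 14 members past 1.5-fold and Spcs1 at -0.42. ER-associated degradation had a median of 0.12 (percentile 98.1) with 0 of 12 past 1.5-fold and the ubiquitin ligase gene Syvn1 highest at 0.50. By the list mean both came inside the random range (percentiles 96.5 and 88.6), and so did ER-associated degradation with no filter on low values (96.3), after centring on mean intensity (97.4) and with the span trend removed (97.3). Unfolded protein response chaperones lay inside the random range, with a median of -0.08 at percentile 31.6, 0 of 17 members past 1.5-fold and 4 members of largest difference, Dnajb9 (0.55), Sdf2l1 (-0.51), Manf (-0.43) and Creld2 (0.28), that went both ways. N-glycosylation genes (median -0.03, percentile 66.1) and the CREB3 family and related factors (median 0.07, percentile 88.1) were inside it too. Among the latter, Creb3 alone of 7 genes passed 1.5-fold. In the list of apolipoproteins and lipoprotein handling, 2 of 13 genes passed, Apoa4 and the receptor gene Lrp1 (0.61), and the median was 0.05 (percentile 94.6).

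**Figure D2:**
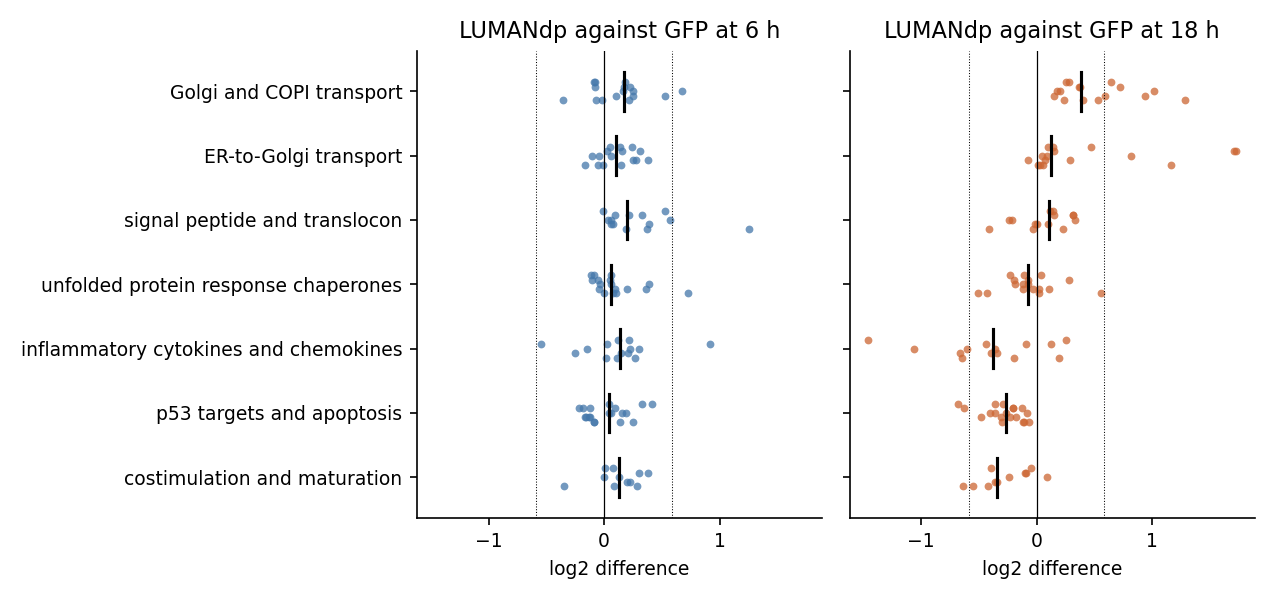
LUMANdp minus GFP difference (log2, horizontal axis) of the members of 7 gene lists (rows) at 6 h (left) and 18 h (right), 1 point per gene, with black bars at list medians and dotted lines at 1.5-fold. At 18 h the Golgi and COPI genes lie to the right of 0 with a median of 0.39, while the inflammatory cytokine and chemokine genes have a median of -0.38.

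Chemokine and other inflammatory genes were lower with LUMANdp than with GFP at 18 h. Ccl7 (-1.46) was the lowest of all genes, and Ccl4 (-1.07) and the acute-phase gene Saa3 (-0.91) were among the 10 lowest. The others were Alyref2 of mRNA export (-1.26), the ribosomal protein gene Rpl35a (-1.22), B3galt6 (-1.05), the Notch effector Rbpj (-1.01), the minor spliceosome gene Snrnp35 (-1.01), Olfr667 (-0.97) and Olfr555 (-0.87). Olfr555 did not pass 1.5-fold with the mean of both GFP arrays as control (-0.11). Rbpj (4.58) and Olfr667 (4.22) were under 4.64 with LUMANdp, so that background limits how exactly their differences and ranks are known. Of 14 inflammatory cytokine and chemokine genes, 5 were at least 1.5-fold lower and 0 higher, with a median of -0.38 (percentile 0.0). Besides Ccl7 and Ccl4 these were Il1b (-0.66), Ccl2 (-0.65) and Ptgs2, the inducible prostaglandin synthase (-0.60). With no filter on low values that list was at percentile 4.75, inside the random range. Costimulation and maturation genes had a median of -0.34 (percentile 0.04), with Tnfsf9 (-0.64) past 1.5-fold and Cd274 at -0.55. The 19 p53 target and apoptosis genes had a median of -0.27 (percentile 0.01), with 2 past 1.5-fold, Casp4 (-0.68) and Plk2 (-0.63). NF-kB feedback genes (median -0.20, percentile 0.58) included Nfkbia at -0.75, and Toll-like and nucleic acid receptors (median -0.18, percentile 0.66) included Tlr2 at -0.77. Macrophage and monocyte markers moved with these groups, at a median of -0.21 (percentile 0.41) with Aif1 at -0.60, and with the span trend removed they came just inside the random range (percentile 2.67). Cholesterol biosynthesis genes had a median of -0.16 (percentile 2.37) with 0 of 16 past 1.5-fold, and came inside against random lists not matched on expression (2.76).

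The split of higher and lower genes at 18 h was 159 to 119 after quantile normalization, 210 to 77 after centring on mean intensity and 218 to 58 with the span trend removed. With other control arrays, the mean of both GFP arrays, which is not matched on time, it was 236 to 245.

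The LUMANdp effect was compared between the times for agreement. Only 5 genes were at least 1.5-fold higher and 5 at least 1.5-fold lower at both times, where independent lists would share 3.38 and 0.22. The higher ones were Creb3, Supt4a (1.73 at 6 h and 0.97 at 18 h), Smim14 (0.61 and 1.15), Uxt (0.66 and 0.85) and Zfp955a (0.72 and 0.72). Lower at both times were Cetn4 (-1.07 and -0.65), Olfr352 (-0.82 and -0.81), Olfr667 (-0.79 and -0.97), Sfn (-0.73 and -0.78) and AY036118 (-1.05 and -0.71), an accession-named gene that was named after its values were seen. Uxt, Olfr352, Olfr667 and Sfn were under 4.64 on at least 1 of the arrays compared. Zfp955a (0.27) and Sfn (-0.29) did not pass at 6 h with the mean of both GFP arrays as control, nor did Olfr352 at 18 h (-0.50). Smim14 did not pass at 6 h after quantile normalization (0.55) or centring on mean intensity (0.57), and with the span trend removed neither Uxt at 6 h (0.55) nor Cetn4 at 18 h (-0.55) passed. Another 5 genes passed 1.5-fold in opposite directions, against 2.53 for independent lists. Across genes, which are not independent replicates, the 2 differences had a Pearson correlation of -0.17 and a Spearman correlation of -0.21, and they share no array. With the span trend removed from both, the Pearson correlation was -0.15.

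**Figure D3:**
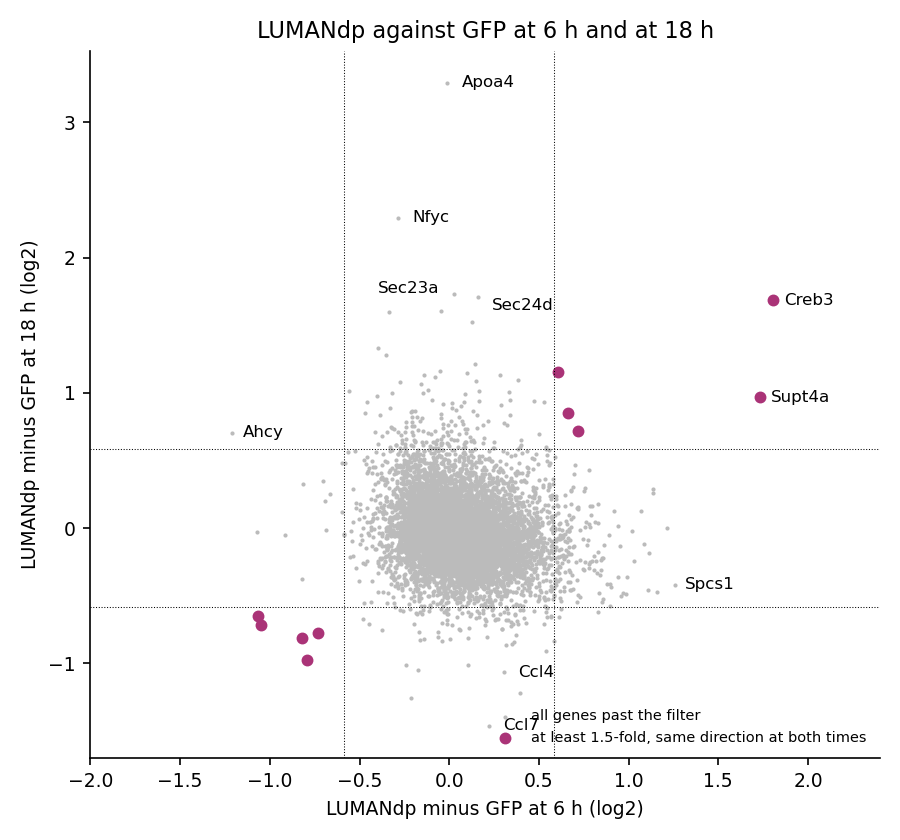
LUMANdp minus GFP difference (log2) at 6 h (horizontal axis) against 18 h (vertical axis), 1 grey point for each of 8584 genes, with dotted lines at 1.5-fold. The 10 genes past 1.5-fold in the same direction at both times are marked, with Creb3 at 1.81 and 1.69, while Apoa4 lies at -0.01 and 3.29.

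In the additive limma model, 2 genes were higher and 2 lower with LUMANdp over both times at an adjusted p under 0.05, and 209 of 8584 genes had an unadjusted p under 0.05. The latter count is under 5% of the genes, the share that evenly spread p-values would give. The error of this model holds any LUMANdp effect that differed between the times, so its p-values need not be evenly spread. The count therefore cannot show whether LUMANdp effects are in excess. Creb3 was higher in both LUMANdp arrays than in the matched GFP arrays, by 1.75 ± 0.17 (SE, limma adjusted p = 0.00138). Supt4a was higher by 1.35 ± 0.20, and Olfr667 and AY036118 differed by -0.88 ± 0.14 each (limma adjusted p = 0.049 for all 3). The residual of this model is the difference between times, so a gene such as Apoa4, with a fitted effect of 1.64 ± 0.49 from 18 h alone, did not pass (limma adjusted p = 0.999). Only 1 gene was higher and 0 lower without the trend, with robust eBayes and after quantile normalization, and with no filter on low values 0 genes passed either way.

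The difference between the 18 h and the 6 h LUMANdp effect has no array left to measure its error, and its sizes are given without a test. At least 1.5-fold, it was positive for 309 genes and negative for 693. Apoa4 (3.30), Nfyc (2.58), Lysmd1 (1.94), Ahcy (1.92) and Tas2r113 (1.72) had the highest values. Ccl7 (-1.68), Spcs1 (-1.67), Cdk10 (-1.63), Rpl35a (-1.61) and Tmem9 (-1.57) had the lowest. Golgi and COPI transport genes lay above random lists (median 0.30, 5 of 16 past 1.5-fold, percentile 100), as did ER-to-Golgi transport genes (median 0.08, 4 of 16, percentile 97.9). Oxidative phosphorylation (median -0.40, percentile 0.0) and inflammatory cytokine genes (median -0.53, 7 of 14 past 1.5-fold, percentile 0.0) lay below. The split was 454 to 453 after centring on mean intensity and 441 to 387 with the span trend removed.

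Cells infected with the control virus were compared with untreated cells, which gives the background against which the LUMANdp effect stands. The untreated cells stood for time 0, and the series holds no array labelled as uninfected cells at 6 h or 18 h. Infection therefore cannot be told apart from the virus supernatant, the coated dishes or the hours in culture. At 6 h, 368 genes were at least 1.5-fold higher and 428 lower in GFP than in untreated cells, and interferon-stimulated genes led the higher ones. Ifit1 (3.91), the chemokine gene Ccl5 (3.48), Rsad2 (3.18), Cxcl10 (3.06), Cmpk2 (2.63), Gbp3 (2.56), Il1a (2.55) and Saa3 (2.48) were highest. The untreated levels of Ifit1 (3.25), Il1a (3.66), Gbp3 (4.10), Ccl5 (4.43) and Myc (4.45) were under 4.64, the 95th percentile of sensory receptor genes, so that background limits how exactly their differences and ranks are known. After centring on mean intensity the split was 404 to 343, and with the span trend removed 401 to 361. Of 19 type I interferon response genes 15 were higher and 0 lower, with a median of 1.69 (percentile 100). Interferon-gamma inducible genes (median 1.11, 4 of 5 higher) and NF-kB feedback genes (median 0.54, 8 of 17 higher and Nfkbiz lower at -1.41) were also at percentile 100. Immediate early genes, which growth and stress signals switch on within minutes, were lower. Of 20, 12 were at least 1.5-fold lower and 1 (Myc, 0.62) higher, with a median of -0.77 (percentile 0.0). Dusp1 (-4.15), Btg2 (-3.13), Nr4a1 (-2.28), Fos (-2.22) and Ier3 (-2.11) were among the 8 lowest genes, with Ccrl2 (-2.40), Pde7b (-2.35) and Cd83 (-2.01).

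Other lists above the random range in GFP against untreated cells at 6 h were ribosome biogenesis (median 0.37, Polr1b 0.95), the NRF2 oxidative stress response (0.25, Slc7a11 1.19), spliceosome genes (0.23, Srsf5 0.68) and macrophage markers (0.19, C1qb 1.04 from 3.72). Below it were oxidative phosphorylation (median -0.26, Cox5a -0.55), conventional dendritic cell genes (-0.45, Mgl2 -1.47 and Id2 -1.04), hypoxia and glycolysis (-0.21, Ndrg1 -1.29), the ATF4 response (-0.19, Ddit4 -1.56), S phase genes (-0.14, Gins1 -0.50) and the proteasome (-0.11, Psmb6 -0.34). With no filter on low values the dendritic cell list was at percentile 39.2 and the macrophage list at 78.9, both inside the range. Removal of the span trend brought the ATF4 (6.36), S phase (3.39), proteasome (3.94) and macrophage (94.4) lists inside it. Random lists not matched on expression did so for hypoxia (2.62), ATF4 (2.82), S phase (7.21) and the proteasome (14.02), centring on mean intensity for S phase (3.79) and macrophage markers (95.7), and the list mean for S phase (2.85).

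At 18 h, 422 genes were at least 1.5-fold higher and 340 lower in GFP than in untreated cells. Pnn (2.73) and Larp7 (2.70), genes of RNA processing, led with Saa3 (2.60), the zinc transporter gene Slc39a7 (2.19), the cohesin gene Smc1a (2.13), Nrd1 (2.06), Gpatch4 (2.01) and Ktn1 (1.98). Dusp1 (-4.14), the chemokine gene Cxcl2 (-4.03), Btg2 (-3.31), Fos (-2.93), Ptgs2 (-2.53), Nfyc (-2.30), Nr4a1 (-2.19) and Jun (-2.08) were lowest. Immediate early genes stayed lower (13 of 20, median -0.92, percentile 0.0). The interferon list was smaller in size, with 6 of 19 higher and 1 lower (Ifit2, -0.77) and a median of 0.43 (percentile 100). Ifit1, the highest gene at 6 h, was 0.13 above untreated. Ribosome biogenesis (median 0.33, percentile 100), signal peptide and translocon (0.25, 99.8), the NRF2 response (0.23, 99.6) and macrophage markers (0.22, 99.1) were above the random range, the last of these not with the span trend removed (96.6). After centring on mean intensity the split was 497 to 239, and after quantile normalization 477 to 258.

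**Figure D4:**
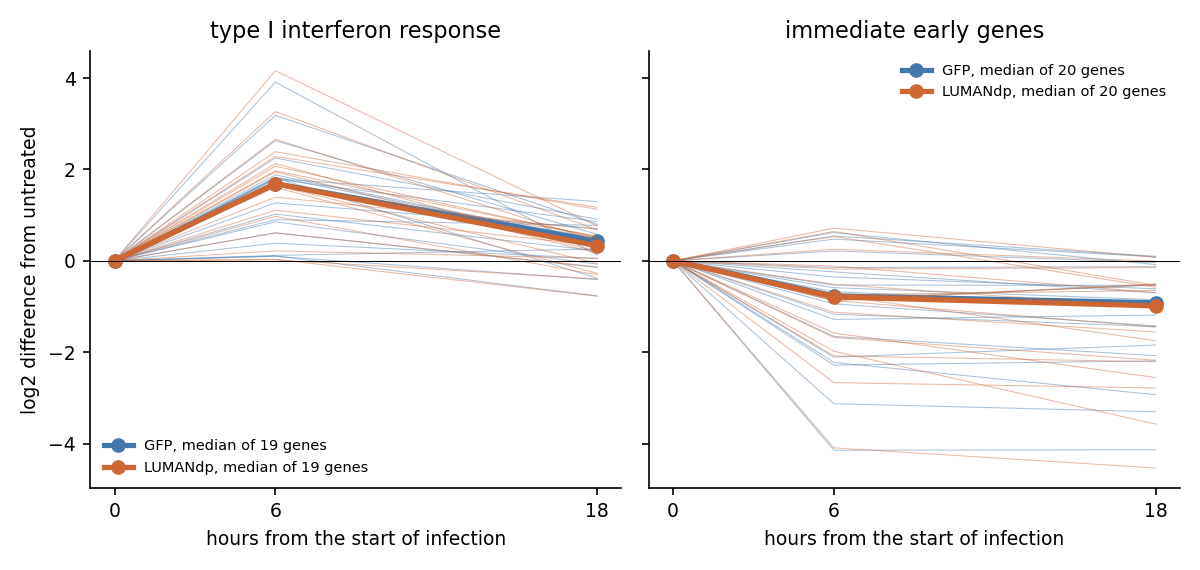
Difference from untreated cells (log2, vertical axis) of 19 type I interferon response genes (left) and 20 immediate early genes (right) at 0, 6 and 18 h (horizontal axis), thin lines for genes and thick lines for medians, GFP in blue and LUMANdp in orange. The interferon medians are 1.69 at 6 h with either virus and 0.43 (GFP) and 0.33 (LUMANdp) at 18 h, and the immediate early medians stay below 0.

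The 6 h and 18 h comparisons of GFP with untreated cells shared 105 higher and 132 lower genes. Simulated unchanged arrays against the same untreated array shared 2.99 and 2.82 on average, and independent lists would share 18.1 and 17.0. The part of the overlap that the shared array brings could not be split off. Pearson's r across genes was 0.50. The simulation gives 0.50 by design, because 2 differences of equal noise share 1 array, so r decides nothing. The covariance was 0.0725 against 0.0219. The simulated noise was taken from LUMANdp minus GFP differences, with a robust spread of 0.20 at 6 h and 0.21 at 18 h. GFP minus untreated had 0.31 and 0.29. If part of that wider spread is noise, the simulated overlap is too low.

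LUMANdp against untreated cells gave 578 higher and 310 lower genes at 6 h and 501 higher and 519 lower at 18 h. The interferon list was 16 of 19 higher at 6 h (median 1.69), and immediate early genes were 13 of 20 lower at 6 h (median -0.79) and at 18 h (median -0.99). Golgi and COPI transport genes had a median of 0.18 at 6 h (1 of 16 higher, percentile 91.0) and 0.54 at 18 h (6 of 16 higher, percentile 100). Unfolded protein response chaperones lay above the random range at 18 h (median 0.16, percentile 99.0, 1 of 17 past 1.5-fold). Inflammatory cytokine genes were 7 of 14 lower and 2 higher at 18 h (median -0.61, percentile 0.0). At 18 h the split was 546 to 417 after quantile normalization, 670 to 294 after centring on mean intensity and 645 to 315 with the span trend removed.

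In the same limma model, 145 genes rose and 305 fell from 6 h to 18 h over both viruses at an adjusted p under 0.05. Ifit1 fell by 3.59 ± 0.16 (SE, limma adjusted p = 1.2e-07). The falls included Cxcl10 (-2.82 ± 0.20), Rsad2 (-2.49 ± 0.18), Ccl5 (-2.48 ± 0.21) and Gbp3 (-2.43 ± 0.17), lower at 18 h in both virus pairs. Ifit1 and Gbp3 were under 4.64 at 18 h, so that background limits how exactly their falls are known. Pde7b (1.92 ± 0.18), Larp7 (1.79 ± 0.19), Pnn (1.52 ± 0.18) and Smc1a (1.47 ± 0.17) rose. Between the 4 infected arrays and the untreated array, the model called 195 genes higher and 97 lower. Its error comes from the infected arrays alone and holds no spread of untreated cultures, so these calls assume that the untreated array varies like the others and are no test against such spread. Dusp1 fell by 4.23 ± 0.21, Cxcl2 fell by 3.08 ± 0.21, Btg2 fell by 2.97 ± 0.20 and Fos fell by 2.68 ± 0.25, in all 4 infected arrays. Ccl5 rose by 2.70 ± 0.24, Saa3 by 2.45 ± 0.29 and Pnn by 2.11 ± 0.20. With no filter on low values the model called 7 higher and 38 lower genes for time, and 10 higher and 18 lower for infection.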

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

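Probe sets with no name in the annotation used here entered none of the comparisons by gene, and some of them differed between the viruses at both times. Of the 7286 such probe sets in the table, 6546 had an identifier number under the lowest named one. What they measure is not known here, and they may not all measure genes. Of 3757 such probe sets past the filter, 52 were at least 1.5-fold higher and 54 at least 1.5-fold lower in LUMANdp than in GFP at 6 h and again at 18 h. Independent lists would share 48.0 and 34.3. A larger number, 163 probe sets, passed in opposite directions, and their count for independent lists was not computed. Across these 3757 probe sets the 6 h and 18 h differences had a Pearson correlation of -0.08. The counts at both times thus show no general agreement between the times. These probe sets were more variable than named genes, since 18.8% of them passed 1.5-fold at 6 h and 25.7% at 18 h.

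For 5 genes the LUMANdp minus GFP difference passed 1.5-fold in opposite directions at 6 h and 18 h, with 1 array per group at each time, and the change between times was not tested. It was 1.92 for Ahcy, which went from -1.21 to 0.70. It was -1.45 for Arl11 (0.83 to -0.62), -1.42 for S100a4 (0.59 to -0.84), -1.27 for Ube2l6 (0.61 to -0.65) and -1.22 for Rida (0.62 to -0.59). These 5 genes were named after their values were seen, except Ahcy. Independent lists would give 2.53 such genes. With the mean of both GFP arrays as control, none of the 5 passed 1.5-fold at both times, and Arl11, Rida, S100a4 and Ube2l6 also missed it at 1 time or both after centring on mean intensity and with the span trend removed.

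The cholesterol and macrophage lists lay above the random range at 6 h and below it at 18 h, and this difference was not tested either. The median change in the LUMANdp effect from 6 h to 18 h was -0.37 for cholesterol biosynthesis, whose median difference went from 0.18 to -0.16. For macrophage and monocyte markers it was -0.27, with medians of 0.18 and -0.21. These calls were not kept under each alternative. With the span trend removed, the cholesterol (percentile 93.5) and macrophage (94.3) lists came inside the random range at 6 h and the macrophage list at 18 h (2.67), and against random lists not matched on expression the cholesterol list did so at 18 h (2.76).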

How the results depend on the processing

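Removal of the genomic span trend, the counts without sensory receptor genes, and the mean of both GFP arrays as control for the count at both times were chosen only after the data were seen. Among named genes past 1.5-fold and gene lists outside the middle 95%, 0 changed direction, but in several comparisons the larger side of the count changed. For GFP against untreated at 6 h, lower genes were more numerous as reported (368 and 428), and higher ones were after centring on mean intensity (404 and 343) and with the span trend removed (401 and 361). For LUMANdp against untreated at 18 h, 501 and 519 became 546 and 417 after quantile normalization, 670 and 294 after centring on mean intensity, and 645 and 315 with the span trend removed. The difference between times went from 309 and 693 to 454 and 453 after centring and to 441 and 387 with the span trend removed. LUMANdp against GFP at 18 h went from 162 and 105 to 236 and 245 with the mean of both GFP arrays as control. Since that control is not matched on time, these counts also hold part of the change in GFP cells between the times. The cause of these changes was not tested, and further ones lie among the counts that follow. Counts are given here as higher and lower genes, in the order LUMANdp against GFP at 6 h and at 18 h, GFP against untreated at 6 h and at 18 h, LUMANdp against untreated at 6 h and at 18 h, and the difference of the LUMANdp effect between times. A 2-fold rule, stricter by construction, gave 13 and 4, 26 and 7, 92 and 81, 144 and 47, 139 and 58, 164 and 68, and 46 and 107, with 1 gene at both times. A filter at the 75th percentile, which leaves fewer genes (4882), gave 97 and 4, 85 and 44, 227 and 157, 245 and 113, 361 and 93, 327 and 204, and 155 and 389, with 4 genes at both times. All 12855 probe sets past the filter, counted alone, gave 471 and 472, 857 and 413, 1234 and 910, 1048 and 1046, 1350 and 847, 1281 and 1068, and 1314 and 1250, with 119 at both times. These include probe sets with no name here. For the results below the cause was not tested. Centring on mean intensity gave 294 lower genes for LUMANdp against untreated at 18 h and 453 for the difference between times. Removal of the span trend gave 99 and 35 genes for LUMANdp against GFP at 6 h, 58 lower at 18 h, 315 lower for LUMANdp against untreated at 18 h and 387 for the difference between times, and 5 lists at 6 h instead of 10. With the mean of both GFP arrays as control, 94 genes were higher at 6 h and 245 lower at 18 h. With the mean of these and the untreated array, 46 were lower at 6 h, and 274 were higher and 209 lower at 18 h. No filter on low values gave 52 lower genes at 6 h and 10 lists for GFP against untreated at 18 h. It also gave 0 and 0 limma calls for virus, 7 and 38 for time, and 10 and 18 for infection, of 14860 genes. For virus limma called 1 and 0 genes without the trend, with robust eBayes and after quantile normalization, and 1 and 1 with the stricter filter, which also gave 87 higher genes for time and 39 lower for infection. The other counts stayed within 1.5 times of those reported. For Creb3 the difference was 1.20 at 6 h and 2.29 at 18 h with the mean of both GFP arrays as control, and 1.65 to 1.81 at either time under the other alternatives. The values with that control also hold part of the rise of Creb3 in GFP cells from 6 h (7.27) to 18 h (8.49). Apoa4 at 18 h stayed between 3.29 and 3.40. Of 468 alternatives for 104 named gene results, 40 fell from past 1.5-fold to under it, 22 of these with the mean of both GFP arrays as control. The other 428 kept their reading. They include Creb3 at 6 h and Apoa4 at both times in GFP against untreated cells, which stayed under 1.5-fold, while the rest stayed past it. List results were recomputed for both comparisons of LUMANdp with GFP and both of GFP with untreated cells, and not for the other comparisons. Of 246 alternatives for these 41 list results, 213 stayed outside the middle 95% and 33 did not, 12 of these with the span trend removed. With 1 array per group, no array could be left out within a group. Signal over background limits genes whose levels lie near those of sensory receptor genes (95th percentile 4.64), such as Uxt, Olfr352 and Olfr667 among the genes that passed at both times.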

Other observations

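The test of the GFP 18 h array, the joining of the ER-to-Golgi and Golgi lists, and the weighing of interferon genes against a culture further along the time course were chosen only after the results were seen. Among immediate early genes at 18 h, 4 of 20 were at least 1.5-fold lower with LUMANdp than with GFP and 0 were higher. They were Ier3 (-0.71), Fos (-0.64) and the MAP kinase phosphatase genes Dusp4 (-0.68) and Dusp6 (-0.62), while the list as a whole lay inside the random range (median -0.11, percentile 14.2). In MHC class I presentation, Tapbpl, a tapasin-related gene, was 0.74 higher at 18 h, with a list median of 0.00 (percentile 73.9). The granulocyte and mast cell list held 2 of 6 genes past 1.5-fold at 18 h, Cebpe (0.91) and Lcn2 (0.60), although its median was -0.19 (percentile 8.27).

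Of 838 sensory receptor genes 37 passed the filter. Since a gene passes by its highest array, these were chosen in part for a high value on 1 array, and how often they pass 1.5-fold is not compared with other genes. Without them, the genes past 1.5-fold in the same direction at both times numbered 8.

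Among named genes, more were higher than lower with LUMANdp at 6 h (179 to 18, a ratio of 9.94). The split was 269 to 438 among probe sets with no name here and 471 to 472 over all probe sets. What the unnamed ones measure is not known here, so these splits do not show whether the excess holds beyond the named genes. The tables argue against an even shift of all named genes, since their median difference was only 0.04. After centring on that median the split was 127 to 23, a ratio of 5.52. Centring does not test a shift that differs between named and unnamed probe sets. Gene length bias stays open, because removal of the genomic span trend left a ratio of 2.83, between the bounds set beforehand for a cause (under 2) and for no cause (4 or more). A GFP 6 h array that stands apart stays open too. Against untreated cells at 6 h, the rho with genomic span was 0.14 for GFP and -0.06 for LUMANdp, which decides nothing with 1 array each. In GFP at 6 h the 179 genes had medians of -0.33 against untreated cells and -0.77 against GFP at 18 h. These medians hold any noise of the GFP 6 h array on which the genes were chosen. Against the mean of the GFP 18 h and untreated arrays, the 179 genes had a median of 0.17 in LUMANdp at 6 h (-0.05 against GFP at 18 h alone and 0.37 against untreated alone), where 0.68 was seen against GFP at 6 h; these values hold any noise of the LUMANdp array on which the genes were chosen, and an effect of LUMANdp stays open, untested.

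Of the 32 ER-to-Golgi and Golgi transport genes, 31 lay above 0 in LUMANdp against GFP at 18 h and 10 passed 1.5-fold, with a median of 0.29. A bias by genomic span as the whole cause is argued against by a median of 0.32 (percentile 100) after the span trend was removed. Transcript length was not tested. A GFP 18 h array that stands apart is argued against by medians of 0.45 against GFP at 6 h and 0.50 against untreated cells, both at percentile 100. A fault of the LUMANdp 18 h array itself was not tested, since no other array of that group exists. A response of these genes to LUMANdp stays open too, untested for the same reason.

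Genes that were higher in GFP at 18 h than in untreated cells were also higher in LUMANdp than in GFP at 6 h, with Pearson's r across genes of 0.37 between these differences, which share no array. A bias by genomic span is argued against, since r was 0.36 after the span trend was removed from both, while transcript length was not tested. A LUMANdp culture further along the time course at 6 h stays open. The 340 genes lower in GFP at 18 h than in untreated cells lay below all genes in LUMANdp against GFP at 6 h (-0.1131 at the median, where -0.1 was the bound set beforehand), but this restates the correlation and decides nothing. Type I interferon genes, whose median difference of GFP at 18 h from GFP at 6 h was -0.93, went the other way, at 0.18 with LUMANdp at 6 h, and their course between the times was not measured.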
